A study of Mus musculus with 35 samples.

How the data were processed

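Expression had been measured by array in 35 samples of sorted mouse mammary cells, in 12 groups of 6 subpopulations and 2 reproductive histories. Groups were taken from the labels, and no column was left unmapped. Per the labels, RNA of 2000 or 10000 cells had been amplified, and the resulting biotin-labelled cDNA was run on 1-colour Affymetrix arrays. The deposited values are log2 expression per probe set, as their range of 1.74 to 13.28 and the near-equal column medians of 5.813 to 5.924 show. The near-equal medians are what a normalization between arrays would leave, and the values are not centred per gene. The labels name the affy software, and its version, the normalization, the background correction, the summary method and the build are not given in the sources used here.

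The table held 34760 probe sets. A supplied annotation table gave a single gene symbol for 21640 of them, several for 1321 and none for 11799. Probe sets with several symbols or none were left out. For 954 genes with more than 1 probe set, the one with the highest mean over all samples was used, which left 19937 genes. Ly6a, Areg and Lalba had no probe set of their own and were not used here.

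Analyses were run in R 4.3.3 with limma 3.58.1. All 35 samples were fitted together as 12 group means with lmFit and eBayes (trend = TRUE), so that groups share 1 estimate of the spread. Contrasts gave the parity effect in each subpopulation (parous minus nulliparous), its mean over the 4 sorted epithelial subpopulations, its differences between subpopulations, and the differences between subpopulations averaged over history. P values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and genes with an adjusted p under 0.05 were called. Standard errors (SE) are those of the moderated fit. A moderated F test was used for differences of the parity effect among all 6 subpopulations. No covariate was used, since the labels state none.

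Genes were named by a fixed rule. For each comparison, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap were eligible, leaving out predicted and family-numbered symbols; for differences between parity effects the condition on overlap was dropped. From each gene list, up to 4 called members per direction were eligible. A fixed panel of milk protein, hormone pathway, Wnt and Notch genes and sorting markers was followed whether called or not. From these, genes whose call held when any single sample was left out were preferred in the text, a choice made after the values were seen.

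The 31 gene lists covered cell type markers and pathways and came from general knowledge. Each was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. The balance of Wnt ligand and Notch genes was tested per subpopulation with a two-sided exact permutation test. The groups, comparisons, tests, gene lists, naming rule and first set of alternatives were fixed before the data were examined.

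The first set of alternatives was eBayes without a trend, array weights, another quantile normalization, leaving out dim probe sets, the mean of all probe sets of a gene, the pool as a random block, the replicate number as a block, the samples of 1 subpopulation alone, and leaving out each sample in turn. Added after seeing the data were leaving out nulliparous pool 1 or 3 in every subpopulation, array weights per subpopulation, pool means taken before the fit, and the mean effect over 3 subpopulations. The numbering of pools across subpopulations is taken from the replicate numbers in the labels, and the correlation of samples with the same number was compared with that under other numberings. Counts were also compared with those of other splits of the samples.

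The fit was tested on simulated data with 200 changed genes among 19937. It recovered 80% to 93% of changes of 1 log2 unit and 97% to 99% of changes of 2 log2 units, depending on the comparison, with 3.57% to 6.86% of calls false and none with the wrong sign. The simulated noise was independent between samples and had 1 spread per gene in all subpopulations. These shares therefore do not cover the wider spread of basal CD49f-high samples, or samples of the same number that deviate together. Overlaps by chance were computed from the numbers of called genes. Raw array files were not analysed here.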

Results

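Gene expression was measured in 35 samples of sorted mouse mammary cells on 1-colour Affymetrix arrays, with 1 array per sample. Parous mice had been mated at 42 days of age, had lactated for 21 days and had then been left for 40 days of involution, the regression of the gland after weaning. Age-matched virgin mice were the nulliparous controls. Each sample pooled cells from the 4th mammary glands of 5 mice, so a replicate is a separate pool of mice. Cells had been sorted into 6 subpopulations: stromal, total epithelial, luminal Sca1-negative, luminal Sca1-positive, basal CD49f-low and basal CD49f-high. Sca1 is the surface protein encoded by Ly6a, and CD49f is integrin alpha 6, encoded by Itga6. Each combination of subpopulation and history had 3 samples, except parous basal CD49f-high cells with 2. Basal CD49f-high samples came from 2000 cells and the other samples from 10000 cells. The number of arrays limits the precision.

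Samples grouped first by cell type. Principal component 1 held 38.1% of the variance and component 2 held 20.6%. Replicates of 10000 cells correlated across genes at Pearson's r of 0.977 to 0.991 over 30 pairs. Replicates of 2000 cells correlated at 0.963 to 0.978 over 4 pairs. The mean spread around the group mean was 0.249 log2 units in basal CD49f-high cells and 0.166 to 0.188 in the other subpopulations.

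**Figure D1:**
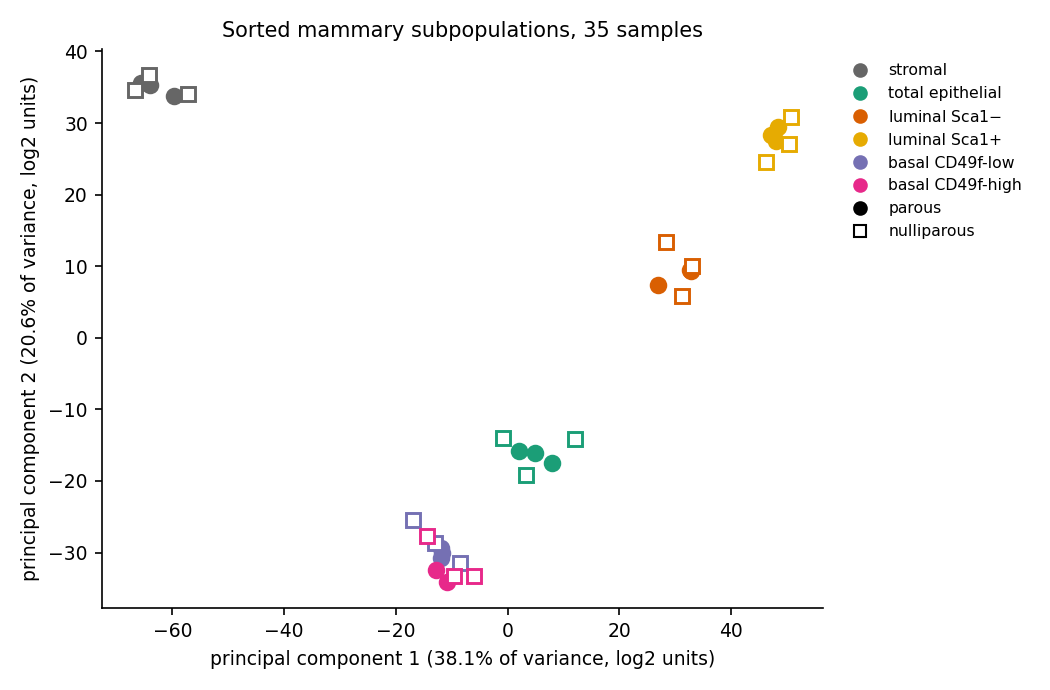
Principal components 1 (38.1% of variance) and 2 (20.6% of variance) of log2 expression, in log2 units, for the 35 samples; colour gives the subpopulation, filled circles are parous and open squares nulliparous samples. Samples sit by subpopulation, with both basal subpopulations side by side and parous samples among or next to nulliparous ones of the same cells.

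Basal cells (both CD49f subpopulations, 11 samples) were compared with luminal cells (both Sca1 subpopulations, 12 samples) to describe the sorted cells, averaging over history. The sodium channel gene Scn7a was higher in basal cells by 5.61 log2 units (SE 0.19). The smooth muscle genes Cnn1 (5.23, SE 0.10), Myh11 (4.69, SE 0.10) and Acta2 (4.47, SE 0.09) and the basal keratin gene Krt5 (4.64, SE 0.09) were also higher. All 10 measured genes of the basal and myoepithelial list were higher in basal cells (median 3.41, camera adjusted p = 1.7e-22, and 1.2e-04 with an estimated correlation). Wnt target genes were higher in basal cells, with 10 of 15 higher and 1 lower (median 0.69, camera adjusted p = 9.8e-07, and 1.7e-04 with an estimated correlation); Lgr5, an R-spondin receptor, was higher by 3.16 (SE 0.08) and Axin2 by 1.02 (SE 0.10). Extracellular matrix genes were higher too, 24 of 28 (camera adjusted p = 1.1e-15, and 0.0054 with an estimated correlation), among them Sparc (3.62, SE 0.09). Markers of other cell types moved with them: fibroblast markers were higher in basal cells in 5 of 10 cases (median 0.31, camera adjusted p = 0.0079; adjusted p = 0.213 with an estimated correlation) and macrophage and dendritic cell markers in 7 of 13 (median 0.42, camera adjusted p = 0.0151; adjusted p = 0.524 with an estimated correlation). Of 11 pan-luminal genes 10 were lower in basal cells, among them Krt19 (-3.03, SE 0.18) and Cldn3 (-1.56, SE 0.09), with a median of -1.56 (camera adjusted p = 1.7e-07; adjusted p = 0.117 with an estimated correlation). In all, 6983 of 19937 genes differed, 3091 higher and 3892 lower in basal cells. Quantile normalization before the fit turned that split to 4292 higher and 3320 lower.

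Luminal Sca1-positive cells (6 samples) were compared with luminal Sca1-negative cells (6 samples). Hormone-sensing genes were higher in Sca1-positive cells: the progesterone receptor gene Pgr by 1.62 (SE 0.19), the estrogen receptor gene Esr1 by 1.25 (SE 0.14), Prom1 by 1.63 (SE 0.19) and Cited1 by 1.53 (SE 0.17). This list had 6 of 8 measured genes higher and none lower (median 1.27, camera adjusted p = 6.2e-08, and 5.1e-04 with an estimated correlation). Luminal progenitor genes were lower, 8 of 10, with the receptor gene Kit at -3.13 (SE 0.19), the transcription factor gene Elf5 at -3.09 (SE 0.20) and Aldh1a3 at -2.51 (SE 0.17). Their median was -2.26 (camera adjusted p = 2.6e-16, and 5.1e-04 with an estimated correlation). Milk protein genes were lower as well, 11 of 15 (median -2.06, camera adjusted p = 3.4e-15, and 5.1e-04 with an estimated correlation), among them Btn1a1 (-2.37, SE 0.13) and Ltf (-3.17, SE 0.31). TGF-beta pathway genes were lower in 10 of 18 cases and higher in 1 (camera adjusted p = 1.6e-07, and 5.1e-04 with an estimated correlation); Tgfb2 differed by -2.25 (SE 0.16). Basal markers moved with these groups: 6 of 10 were lower in Sca1-positive cells (median -0.66, camera adjusted p = 8.1e-06, and 0.0432 with an estimated correlation), among them Cnn1 (-1.52, SE 0.14) and Acta2 (-1.34, SE 0.12). Of all genes 3212 differed, 1794 higher and 1418 lower in Sca1-positive cells.

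Basal CD49f-high cells (5 samples) were compared with CD49f-low cells (6 samples). Itga6 itself differed by 0.00 (0.0036, SE 0.13, adjusted p = 0.992), and Cd24a, the other sorting marker on the arrays, by -0.21 (SE 0.20, adjusted p = 0.612). Ly6a was not measured by a probe set of its own. The proteoglycan gene Lum (-2.03, SE 0.30), Tspan8 (-1.80, SE 0.36), the tryptophan hydroxylase gene Tph1 (-1.65, SE 0.24) and Lgr5 (-0.85, SE 0.12) were lower in CD49f-high cells, and the cell cycle gene Cdca7 was higher by 1.03 (SE 0.19). Fibroblast genes, which mark another cell type, were lower in 2 of 10 cases (median -0.36, camera adjusted p = 1.3e-04; adjusted p = 0.185 with an estimated correlation). Endothelial markers were lower in 2 of 10 cases (median -0.28, camera adjusted p = 0.0044; adjusted p = 0.513 with an estimated correlation), and pan-luminal markers were lower as a group with none of 11 passing in limma and 2 lower adjusted over the list alone (median -0.28, camera adjusted p = 0.0394; adjusted p = 0.678 with an estimated correlation, and 0.0565 after quantile normalization). In all, 705 genes differed, 210 higher and 495 lower in CD49f-high cells. There were 391 without parous CD49f-low replicate 2, 438 without nulliparous CD49f-low replicate 2, 353 without nulliparous pool 3, 268 with array weights and 138 with weights per subpopulation. The number of cells per sample also differed between these subpopulations, which cannot be told apart from the sort.

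Parity was compared within each subpopulation, as parous minus nulliparous on the log2 scale, to find genes that differ after a completed cycle of pregnancy, lactation and involution. Unless a sentence says otherwise, each gene said to rise or fall in 1 subpopulation had all parous values beyond all nulliparous values on that side, in 3 against 3 samples.

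In total epithelial cells the casein gene Csn1s2a (probe set 10522845) rose by 3.62 (SE 0.40, adjusted p = 3.6e-06), from 5.05 ± 0.21 to 8.68 ± 0.12 (SD, n = 3 each). The adhesion gene Hepacam2 (probe set 10542917) rose by 2.26 (SE 0.23), Frmpd4 by 2.05 (SE 0.22) and the neuronal adhesion gene Nrcam by 1.46 (SE 0.16). The keratin gene Krt15 (probe set 10391025) fell by 2.13 on the log2 scale (SE 0.31, adjusted p = 2.6e-04), from 9.52 ± 0.62 to 7.39 ± 0.22 (SD, n = 3 each). Moxd1 (-2.32, SE 0.32), the hyaluronan-binding protein gene Itih2 (probe set 10480003; -1.99, SE 0.28) and Pappa (-1.91, SE 0.29), a protease that cleaves IGF-binding proteins, fell too. Of 15 milk protein genes 2 rose and 13 did not pass (6 higher adjusted over the list alone), with a median of 0.32 (camera adjusted p = 4.3e-07; adjusted p = 0.0526 with an estimated correlation). None of 30 proliferation genes passed in limma over all genes, while 11 were lower adjusted over the list alone. As a group they were lower (median -0.58, camera adjusted p = 2.9e-14; adjusted p = 0.157 with an estimated correlation). Without nulliparous pool 1 in every subpopulation 8 proliferation genes fell (median -0.85), and without nulliparous pool 3 none did (median -0.35). Fibroblast markers moved as well, at 6.67 ± 0.35 in parous and 7.19 ± 0.40 in nulliparous samples (SD, n = 3 each; camera adjusted p = 6.5e-05, adjusted p = 0.0988 with an estimated correlation, and 0.0506 without nulliparous pool 1). In all, 89 genes changed, 33 up and 56 down, and 1448 had an unadjusted p under 0.05. Of all 19937 genes 2995 had no overlap between groups, where chance gives 10%, among them 87 of the 89. The count fell to 29 without parous replicate 2, to 44 without parous replicate 3 (22 up, 22 down) and to 30 without nulliparous replicate 2 (16 up, 14 down), and came to 197 with array weights, 185 with weights per subpopulation and 231 without nulliparous pool 1.

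In luminal Sca1-negative cells Csn1s2a rose by 4.36 (SE 0.40, adjusted p = 1.1e-07), from 5.81 ± 0.29 to 10.16 ± 0.23 (SD, n = 3 each). The milk fat globule genes Btn1a1 (1.57, SE 0.19) and Xdh (1.17, SE 0.22) and the acute phase gene Hp (2.24, SE 0.39) rose with it. Of 15 milk protein genes 3 rose and 12 did not pass, while 9 were higher adjusted over the list alone (median 0.64, camera adjusted p = 2.1e-12, and 0.0055 with an estimated correlation). Csn2 (2.48, SE 0.68, adjusted p = 0.0811) and Wap (0.58, SE 0.15, adjusted p = 0.0535) did not pass. Circadian genes were higher as a group (median 0.38, camera adjusted p = 7.7e-10, and 0.0141 with an estimated correlation); 1 of 14 passed, the clock repressor gene Nr1d1 (1.05, SE 0.18), and 7 were higher adjusted over the list alone. The kallikrein-related peptidase genes Klk11 (-2.04, SE 0.18) and Klk10 (-1.74, SE 0.24), the magnesium channel gene Trpm6 (-2.07, SE 0.21), Itih2 (-1.98, SE 0.28) and the progenitor marker Aldh1a3 (-1.22, SE 0.23) fell. Of 30 proliferation genes 2 fell, among them Birc5 (-1.62, SE 0.28), an inhibitor of apoptosis active in mitosis, and 15 were lower adjusted over the list alone. As a group they were lower (median -0.66, camera adjusted p = 1.1e-11; adjusted p = 0.183 with an estimated correlation). Without nulliparous pool 1, 13 proliferation genes fell, and without pool 3, 2 fell. Basal markers moved with these groups: 3 of 10 rose, among them Krt5 (1.30, SE 0.18) and Cnn1 (1.21, SE 0.20), and their mean was 7.29 ± 0.11 in parous and 6.87 ± 0.18 in nulliparous samples (SD, n = 3 each; camera adjusted p = 1.3e-05, adjusted p = 0.0589 with an estimated correlation). Early response and stress genes were higher, with 1 of 20 rising and 10 higher adjusted over the list alone (median 0.36, camera adjusted p = 1.1e-11; adjusted p = 0.0589 with an estimated correlation). Skeletal muscle markers were lower as a group, with none of 6 passing in limma (median -0.29, camera adjusted p = 0.0071; adjusted p = 0.0796 with an estimated correlation). Wnt4 (-0.17), Tnfsf11 (-0.36), Pgr (0.39) and Esr1 (0.29) did not pass, with SE of 0.13, 0.16, 0.27 and 0.20. In all, 200 genes changed, 132 up and 68 down, 194 of them among the 3522 of all 19937 genes without overlap (10% by chance); quantile normalization moved the share of rises from 66.0% to 55.7%. The count fell to 128 without parous replicate 1, to 113 without parous replicate 2 and to 81 without nulliparous replicate 2, and came to 614 with array weights and 354 without nulliparous pool 1.

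In luminal Sca1-positive cells Csn1s2a rose by 3.42 (SE 0.40, adjusted p = 4.3e-06), from 5.21 ± 1.06 to 8.64 ± 0.64 (SD, n = 3 each). Hepacam2 rose by 2.38 (SE 0.23), the transporter gene Slco1a6 by 2.36 (SE 0.25), the neuropeptide gene Nmu by 2.23 (SE 0.32) and the glycogen phosphorylase gene Pygl by 1.89 (SE 0.19). The defensin gene Defb1 fell by 2.40 on the log2 scale (SE 0.41), Itih2 by 2.32 (SE 0.28), the transcription factor gene Etv1 by 1.69 (SE 0.31) and S100a14 by 1.68 (SE 0.32). Among the 14 circadian genes the clock output factors Hlf (1.30, SE 0.14) and Dbp (0.88, SE 0.12) rose and 12 did not pass (3 higher adjusted over the list alone). That list was higher as a group (median 0.26, camera adjusted p = 6.3e-11, and 0.0124 with an estimated correlation). Milk protein genes were higher too, with 3 of 15 passing and 5 higher adjusted over the list alone (median 0.70, camera adjusted p = 2.8e-08, and 0.0244 with an estimated correlation). None of 30 proliferation genes passed over all genes in limma or over the list alone, though the group was lower (median -0.29, camera adjusted p = 5.1e-06; adjusted p = 0.507 with an estimated correlation). Of the basal markers Krt14 rose (1.54, SE 0.22), and 1 of 10 passed in all (camera adjusted p = 0.0445; adjusted p = 0.507 with an estimated correlation). Endothelial markers sat at 5.95 ± 0.18 in parous and 5.40 ± 0.17 in nulliparous samples (SD, n = 3 each; camera adjusted p = 5.3e-05, adjusted p = 0.427 with an estimated correlation), with none of 10 passing and 3 higher adjusted over the list alone. The panel genes Wnt4 (0.16, SE 0.13), Tnfsf11 (-0.22, SE 0.16), Pgr (0.07, SE 0.27) and Esr1 (-0.08, SE 0.20) did not pass. In all, 121 genes changed, 85 up and 36 down, 119 of them among the 2562 of all 19937 genes without overlap (10% by chance). There were 72 without parous replicate 1, 72 without parous replicate 2 and 77 without nulliparous replicate 2. It came to 194 with array weights, 79 without nulliparous pool 3 and 67 with the samples of this subpopulation alone.

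In basal CD49f-low cells Csn1s2a rose by 2.89 (SE 0.40, adjusted p = 1.2e-04), from 4.32 ± 0.15 to 7.22 ± 0.40 (SD, n = 3 each). Frmpd4 (2.28, SE 0.22), Medag (2.06, SE 0.19), the small proteoglycan gene Ogn (1.78, SE 0.30) and Nrcam (1.52, SE 0.16) rose. Krt15 fell by 2.21 on the log2 scale (SE 0.31, adjusted p = 1.4e-04), Pappa by 2.11 (SE 0.29), the BMP and Wnt antagonist gene Sostdc1 by 1.75 (SE 0.25), the transcription cofactor gene Eya1 by 1.72 (SE 0.26) and Igfbp3, which encodes an IGF-binding protein, by 1.71 (SE 0.28). Of 28 extracellular matrix genes 4 fell, among them the laminin gene Lama4 (-1.11, SE 0.19), and 1 was higher and 9 lower adjusted over the list alone. The list was lower as a group (median -0.28, camera adjusted p = 9.4e-07; adjusted p = 0.170 with an estimated correlation). Of 15 milk protein genes 3 rose and 4 were higher adjusted over the list alone (median 0.24, camera adjusted p = 2.8e-04; adjusted p = 0.170 with an estimated correlation). Fibroblast markers sat at 6.47 ± 0.19 in parous and 7.12 ± 0.24 in nulliparous samples (SD, n = 3 each; camera adjusted p = 4.8e-06, adjusted p = 0.170 with an estimated correlation), with 1 of 10 lower and 4 lower adjusted over the list alone. None of 30 proliferation genes passed in limma, over all genes or over the list alone (median -0.37, camera adjusted p = 8.5e-04; adjusted p = 0.966 with an estimated correlation, and 0.208 without nulliparous pool 3). Lgr5 (-0.09, SE 0.16), Axin2 (-0.20, SE 0.20), Notch1 (0.05, SE 0.17), Jag1 (-0.14, SE 0.25) and Hes1 (-0.07, SE 0.27) did not pass. In all, 193 genes changed, 57 up and 136 down, each among the 2856 of all 19937 genes without overlap (10% by chance). The count fell to 102 without parous replicate 2, to 106 without parous replicate 3 and to 89 without nulliparous replicate 2. It came to 544 with array weights and 62 with the samples of this subpopulation alone.

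In basal CD49f-high cells, with 2 parous and 3 nulliparous samples, Csn1s1 rose by 5.24 (SE 0.95, adjusted p = 6.6e-04), Csn2 by 4.05 (SE 0.76) and the lactoferrin gene Ltf by 3.69 (SE 0.50, adjusted p = 2.1e-05), the last from 6.36 ± 0.45 (SD, n = 3) to 10.05 ± 0.09 (SD, n = 2). Ppp1r14a (2.69, SE 0.29), which encodes an inhibitor of myosin phosphatase, the dystrophin gene Dmd (2.32, SE 0.25), the synemin gene Synm (2.22, SE 0.19) and the oxytocin receptor gene Oxtr (1.43, SE 0.25) rose too. Basal and myoepithelial genes rose in 4 of 10 cases (5 adjusted over the list alone; median 0.49, camera adjusted p = 0.0095, adjusted p = 0.412 with an estimated correlation). Serpinb11 fell by 5.25 on the log2 scale (SE 0.77), the proteoglycan gene Vcan by 3.24 (SE 0.40), Krt15 by 3.22 (SE 0.34), Igfbp3 by 2.55 (SE 0.32) and Lgr5 by 1.58 (SE 0.18, adjusted p = 1.3e-06). The parous mean of Serpinb11 was 3.06, under the cutoff of 5.88 for dim probe sets, so the size of its fall is uncertain. Under this cutoff were also the nulliparous means of Csn1s1 (4.35), Csn2 (5.67), Dmd (5.26) and, named below, Lep (4.96). So were the parous means of Kif11 (4.52), Mcm3 (4.89) and Emcn (4.26), named below. The sizes of these changes are uncertain too. Wnt target genes were lower as a group, with 4 of 15 lower and none higher, both over all genes and adjusted over the list alone (median -0.22, camera adjusted p = 0.0113; adjusted p = 0.0833 with an estimated correlation). The Wnt target gene Axin2 (-0.04, SE 0.22, adjusted p = 0.957) did not pass. Among Notch pathway genes Jag1 (-1.15, SE 0.28, adjusted p = 0.0078) and Notch2 (-0.62, SE 0.16) fell, while Jag2 (0.87, SE 0.17) and Rfng (0.47, SE 0.15) rose. The panel genes Notch1 (-0.38, SE 0.19), Hes1 (-0.19, SE 0.30), Heyl (0.19, SE 0.16) and Hey1 (0.33, SE 0.32) did not pass. Of 30 proliferation genes 13 fell, among them Kif11 (-2.67, SE 0.54), Ccnb2 (-1.52, SE 0.30) and Mcm3 (-1.19, SE 0.24), and 20 were lower adjusted over the list alone. Their median was -0.82 (camera adjusted p = 2.9e-13; adjusted p = 0.332 with an estimated correlation). Without nulliparous pool 1, 18 proliferation genes fell, and without pool 3, 11 fell. Early response and stress genes rose in 11 of 20 cases, among them Fos (1.74, SE 0.24), Hspa1a (1.43, SE 0.23) and Dusp1 (1.02, SE 0.15). Over the list alone 15 were higher (median 0.74, camera adjusted p = 2.9e-13; adjusted p = 0.0833 with an estimated correlation). Of 15 milk protein genes 6 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.54, camera adjusted p = 6.3e-04, adjusted p = 0.264 with an estimated correlation). Some markers of other cell types moved as well. The macrophage marker Cd68 (1.20, SE 0.29) and the adipocyte marker Lep (2.25, SE 0.43) rose, while the endothelial marker Emcn (-2.36, SE 0.74) and the fibroblast marker Fbln1 (-0.95, SE 0.21) fell. In all, 1806 genes changed, 800 up and 1006 down, 1675 of them among the 5520 of all 19937 genes without overlap (20% by chance for 2 against 3). Quantile normalization turned that split to 1060 up and 936 down. The count was 1173 without nulliparous replicate 2, 590 with array weights and 488 with weights per subpopulation. With these 5 samples alone limma called 0 genes, at a smallest adjusted p of 0.0619 and 2101 genes with an unadjusted p under 0.05, so every call in this subpopulation rests on the spread shared with the other samples.

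**Figure D2:**
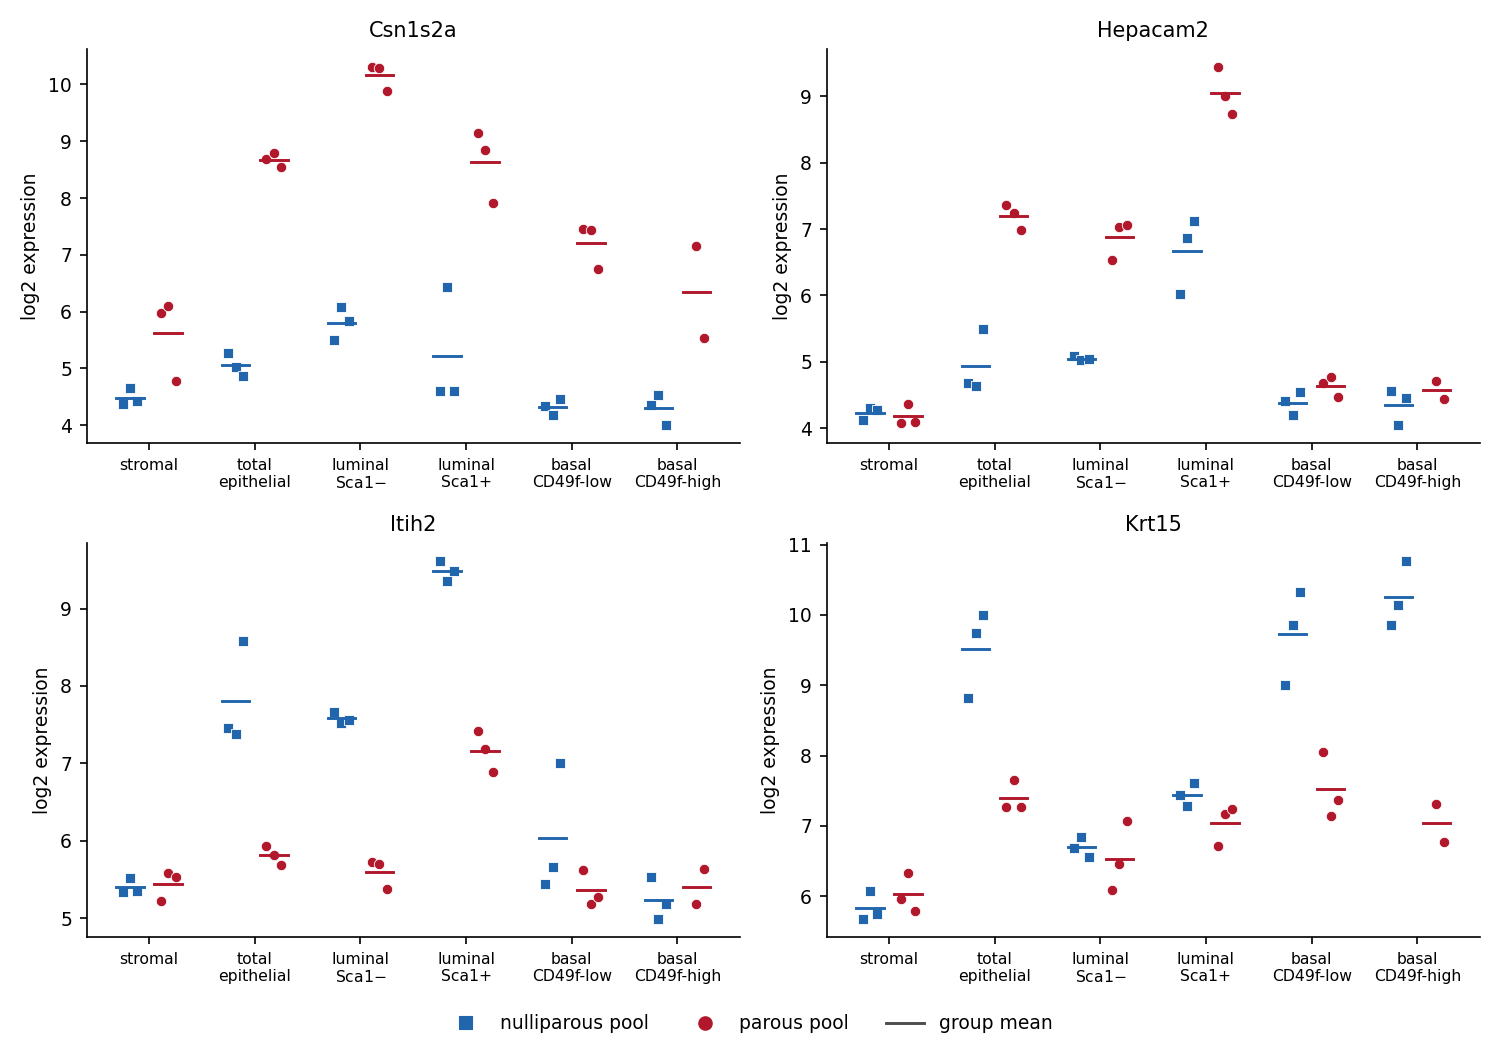
Log2 expression (y axis, log2 units) of Csn1s2a, Hepacam2, Itih2 and Krt15 by subpopulation (x axis); points are single pools, red circles parous and blue squares nulliparous, and short lines are group means. Csn1s2a in parous luminal Sca1-negative cells averaged 10.16 against 5.81 in nulliparous ones, and Krt15 in parous basal CD49f-low cells 7.52 against 9.73.

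In stromal cells the basal keratin genes Krt5 (probe set 10432785) and Krt14 fell. Krt5 went from 7.62 ± 0.23 in nulliparous to 5.77 ± 0.20 in parous samples (SD, n = 3 each), a difference of -1.85 (SE 0.18, adjusted p = 5.7e-07), and Krt14 fell by 2.00 on the log2 scale (SE 0.22). The interferon-induced chemokine gene Cxcl9 (-2.06, SE 0.26), the ubiquitin-like modifier gene Ubd (-3.33, SE 0.47), the cornea and matrix proteoglycan gene Kera (-2.15, SE 0.21), the fibrinogen gene Fgg (-2.16, SE 0.25) and the collagen gene Col3a1 (-0.88, SE 0.15) fell. Fgg was also among the basal-enriched genes used below to test for carried-over basal cells, which predicted 1.95 more of it in nulliparous samples. The deiodinase gene Dio2, whose product activates thyroid hormone, rose by 1.48 (SE 0.18), the melanocyte gene Mlana by 1.28 (SE 0.21) and the complement gene C7 by 0.88 (SE 0.13). Of 10 basal and myoepithelial genes 2 fell and 8 did not pass (3 lower adjusted over the list alone; camera adjusted p = 2.4e-05, adjusted p = 0.152 with an estimated correlation). p53 target genes were lower as a group (median -0.30, camera adjusted p = 1.2e-04, and 0.0102 with an estimated correlation), with Plk2, a stress-induced kinase gene, falling by 1.00 on the log2 scale (SE 0.18) and 14 of 15 not passing (2 lower adjusted over the list alone). Early response and stress genes were lower, with 1 of 20 falling (median -0.14, camera adjusted p = 5.8e-04; adjusted p = 0.419 with an estimated correlation). None of 28 extracellular matrix genes passed over all genes and 1 was lower adjusted over the list alone (median -0.23, camera adjusted p = 7.4e-06; adjusted p = 0.237 with an estimated correlation). Interferon response genes had 1 of 15 lower and 3 lower adjusted over the list alone (median -0.21, camera adjusted p = 0.0073; adjusted p = 0.237 with an estimated correlation). Endothelial markers sat at 6.95 ± 0.17 in parous and 7.56 ± 0.34 in nulliparous samples (SD, n = 3 each; camera adjusted p = 2.4e-05, adjusted p = 0.237 with an estimated correlation). Luminal progenitor markers were at 7.70 ± 0.42 and 8.05 ± 0.58 (SD, n = 3 each), with none of 10 passing in limma (2 lower adjusted over the list alone; camera adjusted p = 0.0034, adjusted p = 0.260 with an estimated correlation), and pan-luminal markers at 7.46 ± 0.73 and 7.68 ± 0.93 (camera adjusted p = 0.0635). Fibroblast markers were at 10.36 ± 0.06 and 10.54 ± 0.13 (SD, n = 3 each; camera adjusted p = 0.0086, adjusted p = 0.294 with an estimated correlation), with 1 of 10 lower. The growth factor gene Igf1 differed by -0.08 (SE 0.26, adjusted p = 0.966). In all, 119 genes changed, 21 up and 98 down, 113 of them among the 3175 of all 19937 genes without overlap (10% by chance). The count fell to 64 without nulliparous replicate 1, and came to 50 with dim probe sets left out and 78 without nulliparous pool 1. With the stromal samples alone it was 18, and of the genes named here Krt5, Krt14, Cxcl9 and Plk2 still passed.

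The mean parity effect over the 4 sorted epithelial subpopulations (11 parous and 12 nulliparous samples) was tested next; a large change in 1 subpopulation can move it by itself. Casein genes were among the rises: Csn1s1 by 3.89 (SE 0.44), Csn1s2a by 3.18 (SE 0.20, adjusted p = 5.0e-11) and Csn2 by 3.18 (SE 0.35). Hp rose by 1.95 (SE 0.20), Irs1, which encodes a substrate of the insulin receptor, by 0.94 (SE 0.15), Nr1d1 by 0.72 (SE 0.09) and Hlf by 0.57 (SE 0.07). S100a14 fell by 1.45 on the log2 scale (SE 0.16), Igfbp3 by 1.30 (SE 0.15) and Aldh1a3 by 0.48 (SE 0.12). Of 15 milk protein genes 7 rose, and 10 were higher adjusted over the list alone (median 0.36, camera adjusted p = 3.6e-13, and 0.0048 with an estimated correlation). Circadian genes rose in 4 of 14 cases (8 adjusted over the list alone; median 0.16, camera adjusted p = 1.6e-07, and 0.0326 with an estimated correlation). Early response and stress genes rose in 14 of 20 cases (17 adjusted over the list alone; median 0.34, camera adjusted p = 3.0e-19, and 0.0175 with an estimated correlation), among them Fos (0.74, SE 0.11) and Dusp1 (0.61, SE 0.07). Of 30 proliferation genes 20 fell and 1 rose, and 25 were lower adjusted over the list alone (median -0.61, camera adjusted p = 1.1e-20; adjusted p = 0.0575 with an estimated correlation). Without nulliparous pool 1, 24 fell, and without pool 3, 14 fell. The division markers Top2a (-1.86, SE 0.27), Mki67 (-1.20, SE 0.19) and Birc5 (-1.06, SE 0.15) were among them. Wnt target genes fell in 4 of 15 cases and rose in 1 (median -0.15, camera adjusted p = 0.0148, 0.0362 with an estimated correlation, and 0.0657 without nulliparous pool 3). Basal and myoepithelial markers were higher on average, 4 of 10 (median 0.28, camera adjusted p = 3.6e-06, and 0.0414 with an estimated correlation). Fibroblast markers were lower, with 2 of 10 falling, Dcn (-0.88, SE 0.13) and Fbln1 (-0.45, SE 0.10) (median -0.25, camera adjusted p = 0.0026; adjusted p = 0.194 with an estimated correlation, and 0.0936 without nulliparous pool 1). In all, 1237 genes changed, 542 up and 695 down. Averaged over both luminal and the basal CD49f-low subpopulations alone, the count was 537 (431 shared with the first), now with 291 up and 246 down, and Fos no longer passed. With the means of these samples per history and number taken first, 3 against 3, it was 133 (78 up, 55 down; 114 shared with the first), and Fos, Dusp1, Top2a, Mki67 and Birc5 did not pass. Without nulliparous pool 3 it was 824. The list tests of the mean effect were not repeated on pool means. Their p values take the samples as independent, although those of the same history and number deviated together across subpopulations.

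**Figure D3:**
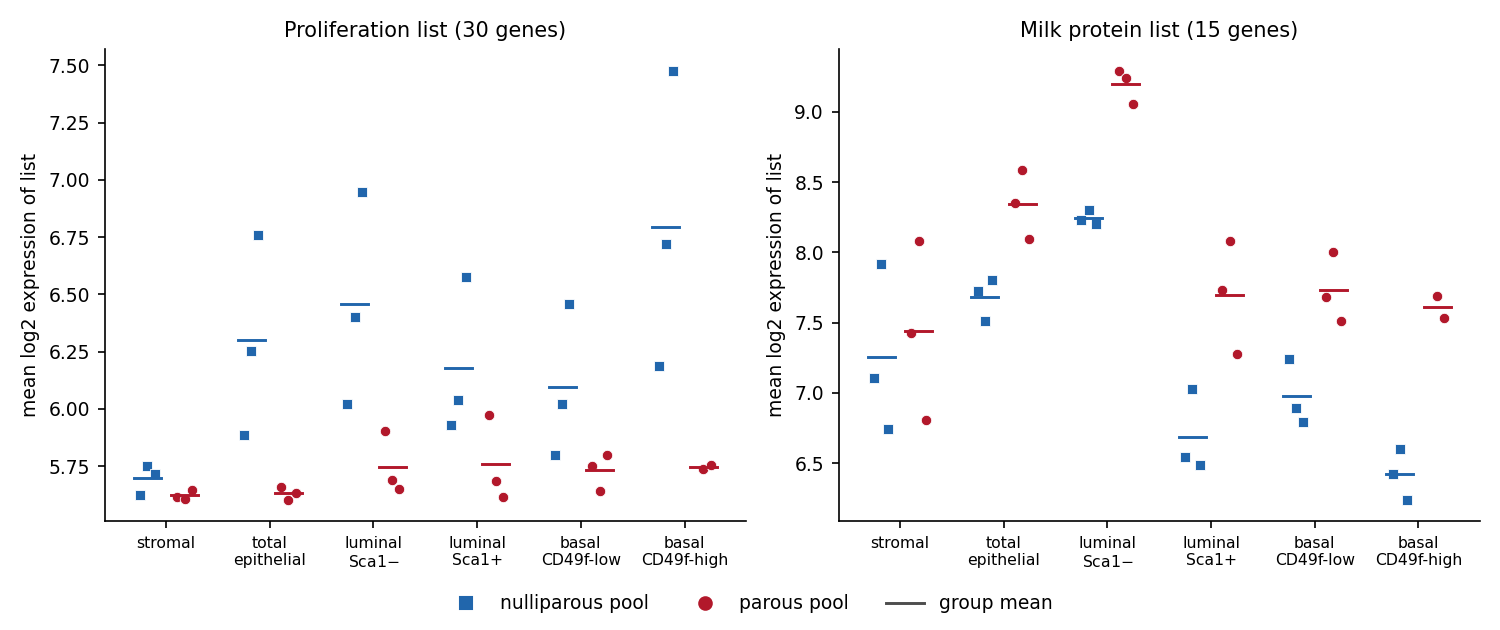
Mean log2 expression (y axis, log2 units) of the proliferation list (30 genes) and the milk protein list (15 genes) per sample, by subpopulation (x axis); points are single pools, red circles parous and blue squares nulliparous, and short lines are group means. In luminal Sca1-negative cells the nulliparous pools sat at 6.02, 6.40 and 6.95 on the proliferation list and each lay above all parous pools.

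Genes called in several subpopulations were counted. Of 2250 genes called in at least 1 parity comparison, 24 were higher and 41 lower in at least 3 subpopulations, and 30 went in both directions. Csn1s2a was called higher in 5 subpopulations, and Hp, Pcdh7, Plcb1 and Sqstm1 in 4. S100a14 and Slco2a1 were called lower in 4. Total epithelial and basal CD49f-low cells shared 20 rises (0.0943 by chance) and 43 falls (0.382 by chance). Both luminal subpopulations shared 16 rises (0.563 by chance) and 3 falls (0.123 by chance), and both basal subpopulations 18 rises (2.29 by chance) and 59 falls (6.86 by chance). Stromal and total epithelial cells shared no gene, with 0.0348 rises and 0.275 falls by chance. These chance values take the comparisons as independent, while samples of the same history and number deviated together across subpopulations, which can raise the overlap by itself. Total epithelial cells were counted as a subpopulation, although by their name they take in the luminal and basal sorts. Overlap between them and these sorts is therefore no separate evidence, and a gene can reach 3 subpopulations through it.

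The parity effect was then compared between paired subpopulations. Between both luminal subpopulations Trpm6 fell in Sca1-negative cells (-2.07) and not in Sca1-positive cells (0.20), a difference of 2.27 (SE 0.29, adjusted p = 2.1e-04). Klk11 differed by 1.63 (SE 0.25) and Syt14, a synaptotagmin gene that rose by 1.77 in Sca1-positive cells, by 1.55 (SE 0.17). The lipase gene Lipm, which rose by 2.17 in Sca1-negative cells, differed by -1.93 (SE 0.29). In all, 19 genes differed, 9 toward Sca1-positive and 10 toward Sca1-negative cells, against 1175 with an unadjusted p under 0.05; after quantile normalization 60.0% rather than 47.4% lay on the Sca1-positive side. The count was 8 without parous Sca1-negative replicate 1, 10 without parous Sca1-positive replicate 2, 30, 9 and 9 without nulliparous Sca1-negative replicate 1, nulliparous Sca1-negative replicate 2 and nulliparous Sca1-positive replicate 2, and 4 with dim probe sets left out.

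Between both basal subpopulations Medag rose in CD49f-low cells (2.06) but not in CD49f-high cells (-0.67), a difference of -2.74 (SE 0.29, adjusted p = 5.1e-06). Lgr5 (-1.49, SE 0.24) and Gch1 (-2.36, SE 0.38), which encodes the first enzyme of tetrahydrobiopterin synthesis, had a lower parity effect in CD49f-high cells; Lgr5 differed by -1.58 with parity there and by -0.09, which did not pass, in CD49f-low cells. Ppp1r14a (2.38, SE 0.39), the potassium channel subunit gene Kcnmb1 (2.74, SE 0.45), Ier2 (1.45, SE 0.24) and the lysosomal protease gene Ctsd (1.15, SE 0.20) had a higher parity effect in CD49f-high cells. Proliferation genes differed as a group (median -0.64, camera adjusted p = 1.1e-05; adjusted p = 0.815 with an estimated correlation), with none of 30 passing in limma, over all genes or over the list alone. In all, 453 genes differed, 197 with a higher effect in CD49f-high cells and 256 with a lower one, and quantile normalization moved the higher share from 43.5% to 57.4%. The count was 283 and 288 without parous CD49f-low replicates 2 and 3, 185 and 755 without nulliparous CD49f-low replicates 1 and 3, 699 and 686 without parous CD49f-high replicates 2 and 3 (with 350 higher and 336 lower for the last), and 865 and 222 without nulliparous CD49f-high replicates 1 and 2. It was 110 with array weights, 71 with weights per subpopulation and 686 with the pool as a random block.

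Between stromal and total epithelial cells the basal keratin genes Krt5 (-2.11, SE 0.25, adjusted p = 9.1e-05) and Krt14 (-2.04, SE 0.31) differed: they fell in stromal cells, and the epithelial differences of 0.26 and 0.04 did not pass. Hepacam2 (-2.31, SE 0.32), Frmpd4 (-2.03, SE 0.31) and Nrcam (-1.67, SE 0.23) rose in epithelial cells, with stromal differences of -0.05, 0.02 and -0.21. Dio2 (1.66, SE 0.25) rose in stromal cells, with an epithelial difference of -0.18. In all, 33 genes differed, 8 with a higher effect in stromal cells and 25 with a lower one, against 1150 with an unadjusted p under 0.05. The count was 18 without parous epithelial replicate 2, 16 without nulliparous epithelial replicate 2, 74 with array weights, 62 with weights per subpopulation and 55 without nulliparous pool 1. Across all 6 subpopulations 558 genes had a parity effect that differed (moderated F test), 352 with weights per subpopulation and 936 with the replicate number as a block.

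The balance of Wnt ligand and Notch pathway genes was compared per sample, as the mean log2 of 23 Wnt ligand and R-spondin genes minus that of 21 Notch genes. In luminal Sca1-negative cells it was -1.06 ± 0.07 in parous and -0.83 ± 0.03 in nulliparous samples (SD, n = 3 each), a difference of -0.23 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). Differences were -0.11 in luminal Sca1-positive cells (exact p = 0.2), -0.10 in basal CD49f-low cells (exact p = 0.3), -0.08 in basal CD49f-high cells (exact p = 0.7), -0.09 in total epithelial cells (exact p = 0.3) and 0.03 in stromal cells (exact p = 0.6). None reached 0.05, which this design cannot do, and adjusted over the 6 tests the p values were 0.45 to 0.7. With dim members left out (9 Wnt and 15 Notch genes) the difference turned to -0.03 in stromal cells (exact p = 0.5). It was then -0.26 in luminal Sca1-negative cells (exact p = 0.1) and -0.03 in basal CD49f-high cells (exact p = 0.9). By camera, the Wnt ligand list was not shifted in the mean parity effect (adjusted p = 0.676). The Notch list was higher there (median 0.05, mean 0.11, camera adjusted p = 0.0243, 0.0440 with an estimated correlation, and 0.188 without nulliparous pool 1), with 2 of 21 genes rising. This list test was not repeated on pool means either.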

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

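Tests chosen after the result was seen were those of free milk RNA, of a mislabelled pool and of a state shared by a pool, and the fits without 1 nulliparous pool and with weights per subpopulation, and the sorting of splits by what they kept apart. For the tests of carried-over cells, results of the pan-luminal and basal lists had been seen, but not the 50 genes tested. The mislabelled pool was placed on milk genes after its place on all called genes was seen.

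The parity effect differed between subpopulations for some genes. Between both luminal subpopulations 19 genes differed (9 and 10 per direction). The parity effect was higher in Sca1-positive than in Sca1-negative cells for Trpm6 (2.27), Vcam1 (1.65), Klk11 (1.63) and Cavin2 (1.58), and lower for Krt5 (-1.22), the growth factor gene Tgfb3 (-1.62), the transcription regulator gene Id2 (-1.72) and Lipm (-1.93). Calls of Trpm6, Klk11 and Lipm held in all 12 fits with 1 sample left out. Vcam1 lost its call in 4 of these fits (adjusted p up to 0.0595), Cavin2 in 9 (up to 0.136), Krt5 in 8 (up to 0.155) and Tgfb3 in 7 (up to 0.109), while Id2 lost it without nulliparous pool 3. Endothelial genes (median 0.54, camera adjusted p = 0.0253; adjusted p = 0.713 with an estimated correlation) and proliferation genes (0.27, 0.0449; 0.874) were shifted toward Sca1-positive cells. Early response genes (-0.24, 8.1e-07; 0.474) and ribosomal protein genes (-0.12, 2.2e-08; 0.265) were shifted toward Sca1-negative cells. Of 100 splits of the 12 samples, the real one included, 15 gave at least as many genes as the real one, with a highest other count of 100, so chance cannot be excluded for this count. Those 14 other splits were among the 26 that kept parous and nulliparous samples apart in 1 subpopulation and so carried its parity effect into the difference. The 73 that kept them apart in neither gave at most 2 genes.

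Between both basal subpopulations 453 genes differed; this count was not compared with other splits. The parity effect was higher in CD49f-high cells for Kcnmb1 (2.74), Rida (2.61), the urotensin-related peptide gene Uts2b (2.60) and Cebpzos (2.39). It was lower there for the cystine transporter gene Slc7a11 (-2.14), Kctd9 (-2.19), Gch1 (-2.36) and Medag (-2.74). Uts2b (adjusted p up to 0.360) and Slc7a11 (up to 0.160) each lost the call in 7 of 11 fits with 1 sample left out. The other 6 genes kept it in all 11. Proliferation genes (median -0.64, camera adjusted p = 1.1e-05; adjusted p = 0.815 with an estimated correlation) and early response genes (0.37, 6.3e-04; 0.815) differed as groups. With weights per subpopulation, which gave basal CD49f-high samples a weight of 0.572 against 0.927 for basal CD49f-low samples in the same fit, 71 genes differed.

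Between stromal and total epithelial cells 33 genes differed. Krt15 (2.32), Itih2 (2.04), Pappa (2.01) and Dio2 (1.66) had a higher parity effect in stromal cells, and Krt14 (-2.04), Krt5 (-2.11), Kera (-2.17) and Hepacam2 (-2.31) a lower one. Krt15 lost its call in 2 of 12 fits with 1 sample left out (adjusted p up to 0.0599), Itih2 in 4 (up to 0.0645) and Pappa in 6 (up to 0.128); the other 5 genes kept it. The parity effect was lower in stromal than in epithelial cells for basal and myoepithelial genes (median -0.28, camera adjusted p = 2.0e-07, and 0.0739 with an estimated correlation). It was also lower for endothelial genes (-0.44, 2.9e-04 and 0.328), milk protein genes (-0.26, 0.0044 and 0.311) and early response genes (-0.48, 2.1e-13 and 0.0739). Involution genes (-0.12, 0.0246 and 0.311), interferon response genes (-0.42, 0.0051 and 0.268) and ribosomal protein genes (-0.04, 0.0113 and 0.525) had a lower parity effect there too. Proliferation genes had a higher one (0.54, 3.9e-07 and 0.525). The ribosomal median turned to 0.02 after quantile normalization. Of 100 splits of the 12 samples, the real one included, 5 gave at least as many genes, with a highest other count of 150, so chance cannot be excluded for this count. That highest split kept both parity effects with 1 of them turned round, and the other 3 were among 16 that kept 1 of them; the 82 that kept neither gave at most 6 genes. Among all 6 subpopulations 558 genes differed in the parity effect, and of 100 splits only the real 1 gave as many, with a highest other count of 442. These splits mixed parous and nulliparous samples within subpopulations and were not sorted by what they kept apart. So they argue against history labels set at random, and cannot decide whether the parity effect was the same in all subpopulations. The real count was lower with weights per subpopulation, and the splits were not repeated with these weights.

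Milk protein genes were higher as a group in parous basal CD49f-low cells (3 of 15 rose; camera adjusted p = 2.8e-04, adjusted p = 0.170 with an estimated correlation), a sort meant to leave out the luminal cells that make milk. Csn1s2a rose there by 2.89, Csn1s1 by 4.07 and Csn2 by 2.73; Csn1s1 lost its call without nulliparous replicates 1 or 3 or parous replicates 2 or 3 (adjusted p up to 0.0663), and Csn2 in all 6 fits with 1 sample left out (up to 0.166). Luminal cells or their RNA, if added in the parous sort alone, would have to make up 15.2% of it, the median over these 3 genes. That share would raise the 50 genes most enriched in nulliparous luminal Sca1-negative over nulliparous basal CD49f-low cells by a median of 0.93. Those genes moved by 0.0090, and observed minus predicted was -0.9 (95% interval -1.05 to -0.76), with 49 of 50 below prediction. At the lowest share of 11.2% the interval was -0.81 to -0.60. These intervals resampled the 50 genes and hold no error between pools. The size of the gap argues against typical luminal cells added in the parous sort alone, while a few cells far richer in casein RNA stay open. A luminal share present in both histories also stays open. With caseins higher in parous luminal cells, it would raise caseins in the basal sort and leave the 50 genes unmoved. That case was not tested. Free milk RNA in the cell suspension would raise caseins in stromal samples as well: the mean of the 3 caseins differed by 1.74 there, where none of them passed in limma, and by 3.23 in basal CD49f-low cells, a difference of -1.49 (exact permutation p = 0.46, 400 arrangements), so this cannot be told apart, and expression by basal cells themselves may remain as a hypothesis.

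Proliferation genes were lower in parous epithelial cells as a group by camera, in the mean effect with an adjusted p = 1.1e-20 and adjusted p = 0.0575 with an estimated correlation; with an estimated correlation the call was lost in each of the 5 epithelial subpopulations (adjusted p of 0.157 to 0.966), and in limma 2 of 30 genes fell in luminal Sca1-negative, 13 in basal CD49f-high and none in the other 3. A parous pool mislabelled as nulliparous replicate 1 would carry milk genes at the parous level: on milk genes called without that pool, 1 to 9 per subpopulation, its median position was 0.10 (-0.30 to 0.25 over 5 subpopulations), where 0 is the other nulliparous samples and 1 the parous ones, against 0.66 to 1.24 for parous pools left out and placed in the same way. That argues against a parous pool, but on all genes called without it the pool sat at 0.44 to 0.50, above the other nulliparous pools (-0.0641 to 0.38) and, except in basal CD49f-high cells, below the parous pools (0.42 to 1.03); what sets this pool apart was not tested. A state shared by all cells of a nulliparous pool, such as its mice or the day, would put the nulliparous pools in 1 order in every epithelial subpopulation, and 5 of 5 subpopulations shared 1 order (chance of 7.7e-04 if the samples were independent). All parous samples lay below in 4 of 5 subpopulations, luminal Sca1-positive cells being the exception. In basal CD49f-low cells this was practically a tie, with the highest parous sample at 5.8002 and nulliparous replicate 1 at 5.8007. Total epithelial cells, by their name, take in the other sorts and are not a separate case. So part of the size of the difference may follow from the state of the nulliparous pools, for which estrous stage is an untested candidate, and a parity effect on proliferation stays open.

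Basal keratin genes changed with parity in sorts that are not basal: Krt5 rose by 1.30 in luminal Sca1-negative cells and fell by 1.85 on the log2 scale in stromal cells. In the luminal sort, Krt5, Cnn1 and Myh11 call for basal cells or their RNA at 3.63%. That share would raise the 50 genes most enriched in nulliparous basal CD49f-low over nulliparous luminal Sca1-negative cells by a median of 0.43. They rose by 0.21, and observed minus predicted was -0.16 (95% interval -0.27 to -0.0239), with 34 of 50 below prediction. This met the bound of 0 set in advance, but the bound was too lax, since the interval left out the error of the share itself: at the lowest share, 3.29% from Myh11, its upper end was 0.0279, so carried-over basal cells cannot be told apart from expression in luminal cells. In the stromal sort, more basal cells in nulliparous samples at 5.61% would put the 50 genes most enriched in basal CD49f-low over stromal cells 0.62 higher there. They were 0.36 higher, and observed minus predicted was -0.26 (95% interval -0.33 to -0.12), with an upper end of -0.0333 at the lowest share of 5.02%. These intervals, like that of the luminal sort, resampled the 50 genes and hold no error between pools. With so small a margin, basal cells as the whole cause or as part of the fall in stroma cannot be told apart.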

How the results depend on the processing

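Added after the results were seen were the fits without nulliparous pool 1 or 3, with weights per subpopulation, with the mean over 3 subpopulations and with pool means taken first, and the comparison with other numberings of the pools; the other alternatives were set in advance. The cause of each change below was not tested unless stated.

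Fits without a trend, with the mean of all probe sets or after another quantile normalization left all 14 counts within 1.5 times their value. Array weights moved 9: total epithelial 197, luminal Sca1-negative 614, luminal Sca1-positive 194, basal CD49f-low 544, basal CD49f-high 590, the difference between the luminal parity effects 63, between the basal ones 110 and between stromal and epithelial ones 74, and basal CD49f-high against CD49f-low 268. Leaving out dim probe sets (10742 genes left) gave 50 in stromal cells and 4 for the luminal difference. With each subpopulation fitted alone, counts were 18 in stromal, 67 in luminal Sca1-positive, 62 in basal CD49f-low and 0 in basal CD49f-high cells by limma (2101 with an unadjusted p under 0.05); by construction this estimates the spread from fewer samples. The pool as a random block gave 686 for the basal difference.

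Without nulliparous pool 1 counts moved to 78 in stromal, 231 in total epithelial and 354 in luminal Sca1-negative cells, 35 for the luminal and 55 for the stromal-epithelial difference. Without nulliparous pool 3 they moved to 79 in luminal Sca1-positive cells, 824 for the mean effect, 12 for the luminal difference and 353 for basal CD49f-high against CD49f-low. Weights per subpopulation moved total epithelial to 185, basal CD49f-high to 488, the luminal, basal and stromal-epithelial differences to 31, 71 and 62, basal CD49f-high against CD49f-low to 138 and the difference among all subpopulations to 352. The mean over both luminal and basal CD49f-low subpopulations gave 537 for the mean effect, and their means per pool taken first 133 (2257 with an unadjusted p under 0.05).

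Parous and nulliparous samples of the same number were not taken as pairs: within a subpopulation their deviations correlated weakly, at r of -0.05 to 0.23, positive in 15 of 17 pairs and over 0.1 in 4. Over all subpopulations the mean r was 0.0483 for the same number (16 of 102 pairs over 0.1), the highest of the 6 ways to number the nulliparous pools (highest other 0.0419). With 6 ways a share under 0.05 is out of reach, so a weak link by number stays open. As a block over all samples the number gave 322 in luminal Sca1-negative cells, 32 for the luminal and 923 for the basal difference and 936 among all subpopulations; within the subpopulation it gave 313 in luminal Sca1-negative cells, and a block of history and number 1134 for basal CD49f-high against CD49f-low.

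Leaving out 1 sample at a time gave ranges of 64 to 123 in stromal, 29 to 95 in total epithelial, 81 to 250 in luminal Sca1-negative, 72 to 104 in luminal Sca1-positive, 89 to 165 in basal CD49f-low and 1173 to 2312 in basal CD49f-high cells. Ranges were 8 to 30, 185 to 865 and 16 to 48 for the luminal, basal and stromal-epithelial differences, and 391 to 976 for basal CD49f-high against CD49f-low. The mean effect (1036 to 1586), the difference among all subpopulations (411 to 777), both luminal subpopulations compared (2768 to 3174) and basal against luminal cells (6634 to 6984) stayed within 1.5 times.

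Of 694 calls of named genes, 693 kept their direction in every alternative, 366 also kept the call in every one, 212 lost it with some sample left out and 302 in another alternative. The exception in direction was Lgr5, at -0.35 in the mean effect and 0.0598 with the mean over 3 subpopulations and with pool means first, both of which by construction leave out basal CD49f-high cells. Genes without a call turned direction as follows. Itga6 in basal CD49f-high against CD49f-low cells went to -0.0379 (array weights), -0.0023 (block of history and number) and -0.0594 (without pool 1). With 1 sample left out it ranged from -0.0748 (nulliparous CD49f-low replicate 1) to 0.0464 and was also negative without parous replicate 3 of either subpopulation (-0.0171 and -0.0225) and without nulliparous CD49f-high replicate 3 (-0.0122). Between luminal subpopulations Itga6 went to -0.0063 (without pool 1). With parity in total epithelial cells it ranged from -0.0454 to 0.0186, positive without parous replicates 2 (0.0076) and 3 and nulliparous replicate 2 (0.0166).

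With parity in basal CD49f-low cells Lgr5 went to 0.0231 (array weights). With 1 sample left out Hes1 ranged from -0.22 to 0.18 (positive without parous replicate 2, 0.0124, and nulliparous replicate 2), Notch1 from -0.13 (without parous replicate 3) to 0.20 and Jag1 from -0.41 to 0.0564 (without nulliparous replicate or pool 3). In basal CD49f-high cells Axin2 went to 0.0203 (quantile normalization) and ranged from -0.22 to 0.26 (without nulliparous replicate or pool 3; 0.0563 without parous replicate 2). Hes1 ranged from -0.75 to 0.36 (without parous replicate 3; 0.0737 without nulliparous replicate 2), Hey1 from -0.41 (without parous replicate 3) to 1.07, Wap from -0.0795 (without parous replicate 2) to 0.23 and Cd24a from -0.16 to 0.0065 (without nulliparous replicate 2). In luminal Sca1-positive cells Cd24a ranged from -0.15 to 0.0460 (without nulliparous replicate or pool 1; 0.0065 and 0.0131 without parous replicate 1 and nulliparous replicate 2), Esr1 from -0.20 to 0.0032 (without nulliparous replicate or pool 1) and Pgr from -0.0212 (without nulliparous replicate or pool 3) to 0.24. In stromal cells Csn3 ranged from -0.28 (without nulliparous replicate or pool 3) to 1.65.

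Of 96 list calls by camera, 23 held with an estimated correlation, 55 with fry, 95 with the replicate block (circadian genes in basal against luminal cells went to 0.0627), 88 without nulliparous pool 1 and 89 without pool 3. Of the 45 in parity comparisons within subpopulations, 6 held with an estimated correlation. The basal list in luminal Sca1-positive cells was lost without pool 1 (0.338), without pool 3 (0.204) and after quantile normalization (0.0827). Quantile normalization also ended the endothelial (0.0538) and proliferation (0.0893) calls of the luminal difference and the involution (0.0789) and ribosomal (0.552) calls of the stromal-epithelial one.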

Other observations

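Tests chosen after the result was seen were the fits without 1 nulliparous pool, the fits of pool means and of the mean over 3 subpopulations, the test of other numberings, and the order of nulliparous pools on the proliferation list; the other tests in this part were planned.

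Further gene groups differed with parity within subpopulations. In luminal Sca1-negative cells, growth hormone and IGF pathway genes were higher, with 3 of 20 rising (median 0.07, camera adjusted p = 0.0011; adjusted p = 0.121 with an estimated correlation), and so were milk lipid synthesis genes, with none of 14 passing in limma (median 0.16, camera adjusted p = 0.0090, and 0.0410 with an estimated correlation; 0.0545 without nulliparous pool 1). The growth factor gene Tgfb3 rose there by 1.55 (SE 0.22) and the matrix gene Tnc by 1.48 (SE 0.25). In luminal Sca1-positive cells the growth hormone and IGF list was called higher (mean 0.17, camera adjusted p = 0.0277; adjusted p = 0.507 with an estimated correlation), although its median was -0.0026 and turned to 0.02 after quantile normalization. In total epithelial cells circadian genes (median 0.26, camera adjusted p = 1.7e-05; adjusted p = 0.0988 with an estimated correlation) and early response genes (median 0.24, camera adjusted p = 5.2e-09; adjusted p = 0.0988 with an estimated correlation) were higher. In basal CD49f-low cells early response genes were higher too (median 0.25, camera adjusted p = 1.7e-07; adjusted p = 0.176 with an estimated correlation), as in luminal Sca1-negative (median 0.36) and basal CD49f-high cells (median 0.74), while they were lower in stromal cells (median -0.14); with an estimated correlation these 3 calls were lost too (adjusted p of 0.0589, 0.0833 and 0.419), and with fry those in stromal (0.340), total epithelial (0.0588) and basal CD49f-low cells (0.0602). In stromal cells milk protein genes were not shifted (median 0.13, camera adjusted p = 0.260), and their mean was 7.44 ± 0.63 in parous and 7.25 ± 0.60 in nulliparous samples (SD, n = 3 each).

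Some genes changed in most epithelial subpopulations at different sizes. Csn1s2a differed by 4.36 in luminal Sca1-negative, 3.42 in luminal Sca1-positive, 2.89 in basal CD49f-low, 2.05 in basal CD49f-high and 1.13 in stromal cells. Its mean over the 12 nulliparous samples of the sorted epithelial subpopulations was 4.91, under the cutoff of 5.88 for dim probe sets. These sizes can therefore not be ranked. S100a14 differed by -1.42 in total epithelial, -1.18 in luminal Sca1-negative, -1.68 in luminal Sca1-positive, -1.25 in basal CD49f-low, -1.68 in basal CD49f-high and -0.12 in stromal cells. Hepacam2 differed by 2.38 in luminal Sca1-positive and 1.83 in luminal Sca1-negative cells, against 0.25 and 0.22 in basal CD49f-low and CD49f-high cells. Krt15 differed by -2.21 and -3.22 in basal CD49f-low and CD49f-high cells, against -0.16 and -0.40 in luminal Sca1-negative and Sca1-positive cells. Differences between luminal and basal parity effects were not tested as such.

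The splits of the samples limit what can be said of the parity counts. With 3 samples against 3 there are 10 splits, too few for a share under 0.05, and in each comparison below 1 split, the real one, gave as many genes. Real and highest other counts were 119 and 32 in stromal, 89 and 8 in total epithelial, 200 and 1 in luminal Sca1-negative, 121 and 3 in luminal Sca1-positive and 193 and 1 in basal CD49f-low cells, and 1237 and 311 for the mean effect with pools split together. Cell type comparisons had 100 splits. As many genes came from 1 split, the real one, for luminal Sca1-positive against Sca1-negative cells (3212 against 1149) and for basal against luminal cells (6983 against 1372). For basal CD49f-high against CD49f-low cells 4 splits, the real one included, gave at least as many as the real 705, the highest 1881. These splits exchanged samples without regard to pool number, and some gave far more genes than the real one. So this share cannot tell the sort from chance or from a structure of the samples, which was not tested.

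Samples of the same history and number deviated together across subpopulations. Their mean correlation was 0.161 in nulliparous samples (28 of 45 pairs over 0.1) and 0.0883 in parous samples (15 of 40). Of 7776 numberings of the nulliparous and 2592 of the parous samples within their groups, only the real 1 gave a mean as high (highest other means 0.134 and 0.0780). Nulliparous replicate 1 correlated with itself over 15 pairs of subpopulations at 0.0553 to 0.338, with a median of 0.197. A shared pool of mice or day of work may lie behind this. The 1 order of nulliparous pools on proliferation genes, shared by 5 of 5 epithelial subpopulations, comes from the same samples and is no separate support. For the mean effect the count was 1237, 874 with the pool as a random block, 537 without basal CD49f-high cells in the mean and 133 with pool means of these 3 subpopulations first. So part of the lower count comes with leaving out basal CD49f-high cells, and the rest of that step also has fewer residual degrees of freedom, which was not separated from the sharing of pools.

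Itga6 transcript differed by 0.00 between CD49f-high and CD49f-low cells, at 10.75 ± 0.07 (SD, n = 5) and 10.74 ± 0.21 (SD, n = 6). CD49f had been sorted as surface protein, and transcript and protein level need not go together. Whether the gates differed between histories was not analysed here.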
